A study of Homo sapiens with 11 samples.

How the data were processed

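The series holds 9 poly(A)-enriched, stranded, paired-end libraries of Jurkat E6-1 cells (3 each with DMSO, dieldrin and PMA, 30 min) and 2 ribosomal RNA-depleted libraries (1 DMSO, 1 dieldrin). RNA was extracted with phenol and chloroform and the libraries were primed with random hexamers, per the labels. The submitters' processing notes name STAR, edgeR and the build hg19, without settings; the aligner settings, the counting tool and its use of strand, the site caller and the annotation release are not given in the sources used here, so genes that overlap another gene on either strand, and near-identical copies, carry an uncertain share of reads.

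Per the file headers, the authors' comparison table for each treatment gives per gene a mean normalised count (signal), a shrunken and an unshrunken log2 fold change against DMSO (log2), a standard error of the shrunken change and a Wald statistic (score), and a p-value and an adjusted p. Per the file headers the column names are those of DESeq2 results with a fold-change prior, although the authors' notes name edgeR. The shrunken change divided by its standard error equals the statistic for every gene, and the mean is the same in both sheets for all 44416 genes. Gene positions and the site lists are on hg19, and site positions are printed counted from 1. A p-value is missing for 1088 genes, and further genes of low mean have no adjusted p; the lowest adjusted mean is 5.13 with dieldrin and 9.44 with PMA.

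No values per library were used, so the depth of each library is unknown, the authors' fold changes and adjusted p-values were taken as they stand (threshold 0.05), and no count model was fitted. CPM is a gene's mean normalised count over the sum of all means, on the usual CPM scale. Mean levels per group were worked out from the 2 unshrunken changes and the mean, taken as the mean over the 9 libraries. Dieldrin was set against PMA by the difference of the shrunken changes with the root of the summed squared standard errors, a normal two-sided test, and Benjamini-Hochberg adjustment over genes adjusted in both sheets. This leaves out the covariance from the shared DMSO libraries, which by itself enlarges the error, but shrinkage can make the error too small for single genes. The dispersion implied by the changes and statistics was used to simulate 20 sets of unchanged groups against shared controls; a control group of 3 cannot be split.

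The 28 gene lists, 640 symbols of which 635 were found, were fixed beforehand and tested by limma 3.58.1 (R 4.3.3) with cameraPR on the authors' Wald statistic, preset correlation 0.01, against all genes with an adjusted p, with Benjamini-Hochberg adjustment over lists of 3 or more tested members. An estimated correlation needs values per library and was not possible. Gene types came by gene ID from GENCODE v29, which matched 41842 of 44416 IDs; its coordinates were not used.

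Sites overlapped when they shared at least 1 bp. Sites near a gene lay within 10 kb of its start or in its body, and shares were compared with 10000 random sets of uncalled genes drawn from 20 bins of mean expression (seed 20). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. For the closing section, hydrophobic segments were windows of 19 residues with a mean Kyte-Doolittle hydropathy of at least 1.6 in the longest coding sequence of each gene in GENCODE v29.

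Named genes followed a rule fixed beforehand: per comparison, among called genes of at least 1 CPM, the 6 largest rises and 6 largest falls by the shrunken change and the 3 smallest remaining p-values; up to 3 members of smallest p from each list; and 19 genes always named. For sites, the 5 of each list nearest to the start of a named gene were taken, ties going to the gene of smaller p. Further called members of a list, and NR4A3, SLA, NOTCH2, NOTCH3 and the mitochondrial tRNA group, were chosen after their values were seen. Some genes that the rule names are not reported here.

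The steps were tested on simulated data. Among 17587 simulated genes with 3 libraries per group and 100 genes set to differ between dieldrin and PMA, the test of the difference, run there on unshrunken changes without covariance, recovered 11 of 25 at a log2 difference of 0.5, 19 of 25 at 1, and all 25 at 2 and all 25 at 4, with 0 false calls. With the implied dispersion 90 of the 100 were recovered and 8 calls were false, 8.16% of its calls. The Wald test of dieldrin against DMSO recovered 182 of 200 with 11 false, 5.7%. All changed genes had means above 100 counts, and the tests were given the true dispersion. The simulated statistics were made from unshrunken changes, whereas the authors' statistic belongs to the shrunken change. These rates therefore do not cover changed genes of lower mean, an estimated dispersion or genes with strong shrinkage. Alternatives were other thresholds, expression filters and adjustments, other window and overlap rules, and some settings chosen after seeing the data.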

Results

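Gene expression was measured by RNA sequencing in Jurkat cells, clone E6-1, an established human T cell leukaemia line, after 30 min with the solvent DMSO, with 100 µM of the organochlorine insecticide dieldrin, or with 100 µM of the phorbol ester PMA, a direct activator of protein kinase C. Both doses are given as labelled; that of PMA is far above those in common use and is uncertain. The poly(A)-enriched libraries formed 3 groups of 3. A further pair of libraries, 1 from DMSO and 1 from dieldrin cells, was depleted of ribosomal RNA, and from each the authors deposited a list of sites of divergent transcription on genome build hg19. For the poly(A) libraries the values used here are the authors' own comparisons of each treatment with DMSO for 44416 genes. Levels are given as CPM, the share of a gene in the summed mean normalised counts, where 1 CPM is a mean of 83.7 counts; 12853 genes reached it. The depth of the single libraries is unknown from these values. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values cover the spread between these libraries, which may be technical.

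The first comparison asks which RNAs changed within 30 min of dieldrin. Immediate-early transcription factors were among the genes that rose most: JUN, EGR1, EGR2 and FOS rose together with the early activation marker CD69, the phosphatase DUSP1 and the NF-kB inhibitor NFKBIA. Heat shock genes also rose, among them HSPA1A, HSPA1B and DNAJB1. ATP13A2, a lysosomal transport ATPase gene, PNPLA6, the gene of neuropathy target esterase, and 11 of 20 mitochondrial tRNA genes fell. Of 21 genes listed for NRF2 and oxidative stress, 0 rose and 2 fell, TXNIP and ABCC1.

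The authors' deposited table of dieldrin against DMSO adjusts the p-values of 19280 genes, of which 443 had an adjusted p under 0.05. Among these 443 genes in the authors' deposited table, 246 were higher and 197 lower with dieldrin. By the unshrunken estimate 96 of the higher and 29 of the lower genes changed 2-fold or more. The median fold of the higher genes was 1.72 and that of the lower genes 0.685. Protein-coding genes made up 180 of the 246 higher and 135 of the 197 lower genes, and long noncoding RNAs 31 and 41.

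JUN (ENSG00000177606, chromosome 1, 59246465 to 59249785) had the smallest p, and the authors' deposited table gives it a shrunken log2 fold change of 3.67 with a standard error of 0.109 and an adjusted p of 1.66e-246. Without shrinkage the authors' deposited table puts JUN at 38.8-fold. CD69 (ENSG00000110848, chromosome 12, 9905082 to 9913497) follows in the authors' deposited table with 3.64 ± 0.111 (shrunken log2, SE), 43.9-fold unshrunken and an adjusted p of 2.11e-232. EGR1 (ENSG00000120738, chromosome 5, 137801179 to 137805004) stands at 2.51 ± 0.116 in the authors' deposited table, with 39.3-fold unshrunken and an adjusted p of 3.54e-101. EGR2 rose 86.0-fold, unshrunken, in the authors' deposited table. For IER2 the authors' deposited table gives 7.53-fold, for DUSP1 6.59-fold, for NFKBIA 5.98-fold and for MCL1 2.94-fold, with adjusted p-values of 1.59e-96, 6.30e-106, 6.14e-102 and 7.00e-111. FOS had a wide gap between its estimates in the authors' deposited table, with a log2 fold change of 1.66 after shrinkage and 8.10 before it, and an adjusted p of 3.61e-62. The mean normalised counts these values imply for FOS are 54.9 with DMSO and 15120 with dieldrin. TNF carries no p-value in the authors' deposited table although its unshrunken change is 86.7-fold, so it is not counted as called.

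The lists fixed beforehand place these genes in groups. The list of immediate-early transcription factors also holds early genes of other kinds, such as ZFP36, ARC and IER3. Of its 32 genes tested, 22 rose, 0 fell and 10 did not pass the test. Adjusted over the list alone, 24 rose and 1 fell. Their median unshrunken log2 fold change was 1.21, and the limma set test (cameraPR) gave an adjusted p of 2.43e-221 over the lists. Of 27 MAPK feedback genes, 8 rose (9 adjusted over the list alone), led by DUSP1, DUSP2 and RGS2. Of 21 NF-kB genes, 4 rose (7 adjusted over the list alone), and of 13 activation receptors and markers 3 rose, namely CD69, ICOS and CD83 (4 adjusted over the list alone). CCL4 and CCL5 were the 2 of 13 cytokines and chemokines that rose (4 adjusted over the list alone), at 0.134 and 0.0720 CPM. IL2 did not pass, with an adjusted p of 0.743 in the authors' deposited table. Of 24 heat shock and chaperone genes, 6 rose and 0 fell (8 rose adjusted over the list alone), and the set adjusted p was 3.09e-08. HSPA1A rose 7.27-fold, HSPA1B 6.11-fold and DNAJB1 3.22-fold, unshrunken, in the authors' deposited table, with adjusted p-values of 4.41e-08, 4.86e-09 and 2.19e-11. HSPA1A and HSPA1B are near-identical, so how their reads were divided is uncertain. Of 25 unfolded protein and integrated stress response genes, 4 rose (6 rose and 1 fell adjusted over the list alone), among them PPP1R15A at 4.53-fold and DDIT3 at 2.16-fold in the authors' deposited table. Of 18 snoRNA host genes, 6 rose (9 adjusted over the list alone), with SNHG3 at 1.42-fold in the authors' deposited table. Of 24 replication-dependent histone genes 3 rose (5 adjusted over the list alone). Which forms of histone RNA these poly(A)-enriched libraries captured is unknown. As sets, the lists of this paragraph were higher, with adjusted p-values of 4.36e-17 for MAPK feedback, 5.73e-20 for NF-kB, 6.58e-19 for activation markers, 0.000677 for cytokines, 5.00e-06 for the stress response, 6.13e-15 for snoRNA hosts and 0.0140 for histones. An estimated correlation between genes could not be had for these tests. With preset correlations of 0.05 and 0.1 in place of 0.01, the histone list lost its call (adjusted p 0.0930 and 0.215) and the others kept theirs. With ranks in place of the statistic the stress response (0.211), activation marker (0.0531) and histone (0.119) lists lost theirs, and at 1 CPM or more the cytokine list did (0.712).

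Other stress and toxicity lists moved little with dieldrin. Of 21 genes of the list of NRF2 and oxidative stress, which holds regulators as well as targets, 0 rose, also at an unadjusted p under 0.05, while 2 fell; adjusted over the list alone the count was also 2. TXNIP fell by 0.67 and ABCC1 by 0.30 on the shrunken log2 scale in the authors' deposited table. HMOX1 had a mean of 0.929 normalised counts in the authors' deposited table and no adjusted p. In the xenobiotic metabolism list 1 of 7 rose (1 adjusted over the list alone), TIPARP at 1.41-fold in the authors' deposited table, and CYP1A1 did not pass, with an adjusted p of 0.808 in the authors' deposited table. The p53 list had 3 of 21 genes higher, PMAIP1, PLK3 and PPM1D (3 adjusted over the list alone), and the metallothionein and zinc list 1 of 4, SLC30A1 (1 adjusted over the list alone). Of 24 cholesterol genes 1 rose (1 adjusted over the list alone). BRD2 alone rose among 23 elongation genes, ZCCHC8 among 21 RNA exosome and decay genes and CLK1 among 24 splicing genes; adjusted over the list alone these counts were 1, 1 and 2. Of these lists the splicing list alone passed as a set (adjusted p 0.0436, lost at 0.173 with a preset correlation of 0.05 and at 0.0599 at 1 CPM or more). None of 22 interferon-stimulated genes, 51 ribosomal protein genes or 4 GABA-A receptor subunits passed in the authors' test, and at an unadjusted p under 0.05 the counts were also 0. Of 24 glycolysis and hypoxia genes 0 passed, with 1 higher and 1 lower at an unadjusted p under 0.05. The p53 and xenobiotic lists had a median log2 change below 0 and an upward set test and the interferon list a mean above 0 and a downward one, all short of the threshold.

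Among the 197 lower genes, the 6 largest falls at 1 CPM or more, by the shrunken change, were those of ATP13A2, PNPLA6, MT-TY, CBX6, CTD-2227E11.1 and MT-TT. ATP13A2 (ENSG00000159363, chromosome 1, 17312453 to 17338423), mutated in a familial parkinsonism, fell by 0.93 in shrunken log2 units with a standard error of 0.106 and an adjusted p of 5.67e-16 in the authors' deposited table. PNPLA6 (ENSG00000032444, chromosome 19, 7598890 to 7626650) fell by 0.91 with a standard error of 0.104 and an adjusted p of 1.09e-15 in the authors' deposited table. With SORL1, ATP13A2 made 2 of 16 Parkinson and Alzheimer disease genes lower (2 adjusted over the list alone), and 0 rose, also at an unadjusted p under 0.05. This list passed as a set, lower with an adjusted p of 0.0280, and lost its call at 0.0987 with a preset correlation of 0.05, 0.387 with ranks and 0.0719 at 1 CPM or more. NOTCH1 and RAG1 were the 2 of 27 T cell receptor and T-ALL identity genes that fell (2 adjusted over the list alone), with adjusted p-values of 0.0277 and 0.0374 in the authors' deposited table; both missed the threshold when the adjustment covered all listed genes. Chosen after their values were seen, NOTCH2 and NOTCH3 fell by 0.71 and 0.63 on the shrunken log2 scale in the authors' deposited table.

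Mitochondrial transcripts moved unevenly. In these poly(A)-enriched libraries, the forms of mitochondrial tRNA that gave the reads are unknown. All 20 mitochondrial tRNA genes tested were lower with dieldrin and 11 passed, a group singled out after its values were seen. Their unshrunken log2 changes ran from -2.33 to -0.15, with a median of -1.02. The 13 mitochondrial mRNAs were all lower as well, with a median of -0.18; 0 passed in the authors' test (1 adjusted over the list alone, 4 at an unadjusted p under 0.05), although with the rescaled statistic MT-ND6 (adjusted p 0.000103), MT-CO1 (0.00817) and MT-CO3 (0.0336) did, and the set adjusted p was 0.00581, or 0.0809 with a preset correlation of 0.1. Control genes were not called: GAPDH, ACTB and CD3E had unshrunken folds of 0.972, 1.08 and 0.978 in the authors' deposited table, with adjusted p-values of 1.00, 0.961 and 1.00.

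The second comparison asks the same of PMA. At 1 CPM or more PMA raised EGR1, CD69, NFKBIA, IER2, JUNB and the kinase gene SGK1 most by the shrunken change; unshrunken, several others rose more. It raised the NF-kB inhibitor genes NFKBIA and TNFAIP3 and the activation marker CD83. Of 24 heat shock genes 0 passed. Most of the genes it lowered were long noncoding RNAs. The authors' deposited table of PMA against DMSO adjusts 17612 genes, of which 109 had an adjusted p under 0.05, and 93 of these were higher and 16 lower. Of these, 40 and 4 changed 2-fold or more unshrunken. With the statistic rescaled to its own spread, a setting chosen after the data were seen, 288 genes were higher and 95 lower.

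EGR1 rose 49.1-fold and CD69 13.1-fold with PMA, unshrunken, in the authors' deposited table, with adjusted p-values of 4.14e-119 and 2.11e-93. NFKBIA (ENSG00000100906, chromosome 14, 35870717 to 35873955) had a shrunken log2 fold change of 2.22 ± 0.094 (SE), a fold of 6.84 and an adjusted p of 3.00e-118 in the authors' deposited table. IER2, JUNB, IER3 and SGK1 rose 6.85-, 6.60-, 5.71- and 5.24-fold in the authors' deposited table, and MCL1 and SNHG3 rose 2.92- and 1.65-fold. JUN rose 5.81-fold, EGR2 14.0-fold, DUSP1 2.40-fold, DUSP2 8.54-fold and NFKBIZ 8.74-fold with PMA, unshrunken, in the authors' deposited table. TNFAIP3 was raised 2.47-fold and CD83 2.91-fold by PMA in the authors' deposited table. MYCN fell by 0.52 and the noncoding RNA CTD-2227E11.1 by 0.76 on the shrunken log2 scale in the authors' deposited table. Of the 16 lower genes, 12 were long noncoding RNAs.

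By list, PMA raised 12 of 31 immediate-early list genes (17 rose and 1 fell adjusted over the list alone, set adjusted p 5.17e-127). It raised 4 of 21 NF-kB genes, NFKBIA, NFKBIZ, TNFAIP3 and BIRC3 (9 adjusted over the list alone), with a set adjusted p of 6.79e-51. Of 27 MAPK feedback genes 5 rose (7 adjusted over the list alone), and of 11 activation receptors and markers 2, CD69 and CD83 (2 adjusted over the list alone). Of 10 cytokines and chemokines tested 0 passed, with 2 higher at an unadjusted p under 0.05. In the heat shock list 0 genes passed (1 adjusted over the list alone, 3 at an unadjusted p under 0.05), and with the rescaled statistic DNAJB1 (adjusted p 4.05e-13) and HSPA8 (2.46e-06) did, while the list as a set was higher, with an adjusted p of 0.00167, or 0.0978 with a preset correlation of 0.1. Of 25 unfolded protein and integrated stress genes 3 rose (3 adjusted over the list alone), PPP1R15A, DDIT3 and DNAJB9. Of 18 snoRNA host genes 4 rose (8 adjusted over the list alone), and of 23 elongation genes 2, BRD2 and HEXIM1 (2 adjusted over the list alone). The cholesterol list was higher as a set, with an adjusted p of 1.59e-05, although only 1 of its 24 genes passed (2 adjusted over the list alone). SLC30A1, PMAIP1 and SLC2A3 were the single called genes of the metallothionein, p53 and glycolysis lists, each with 1 adjusted over the list alone. PMAIP1 and HEXIM1 missed the threshold when the adjustment covered all listed genes. As sets, the lists of MAPK feedback (adjusted p 4.25e-16), activation markers (1.98e-23), unfolded protein and integrated stress genes (9.76e-10), snoRNA hosts (1.98e-23) and metallothioneins (0.00887) were higher. With ranks in place of the statistic the MAPK feedback (0.0933), activation marker (0.162) and metallothionein (0.159) lists lost their calls, while the exosome (0.00342) and ribosomal protein (0.0287) lists, not called with the statistic (0.150 and 0.474), were higher. In the other lists 0 genes passed the authors' test with PMA. At an unadjusted p under 0.05 these had 3 splicing genes, 1 NRF2 and oxidative stress, 1 xenobiotic, 1 histone, 1 Parkinson and Alzheimer gene and 1 myeloid marker higher, and 1 T cell identity gene lower. The count was 0 for 21 exosome, 20 interferon, 51 ribosomal and 13 mitochondrial mRNA genes tested. It was also 0 for the few tested of the GABA-A (3), B cell (5) and fibroblast and epithelial (1) lists. In the erythroid and platelet list 0 genes were tested with PMA. Adjusted over the list alone, 2 splicing genes and the 1 myeloid marker passed and 0 of the others. The splicing list was higher as a set (adjusted p 0.00342, or 0.124 with a preset correlation of 0.1). The histone, elongation and myeloid lists had a median log2 change below 0 and an upward set test, the xenobiotic list a mean below 0 and an upward one and the B cell list a mean above 0 and a downward one, all short of the threshold.

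**Figure D1:**
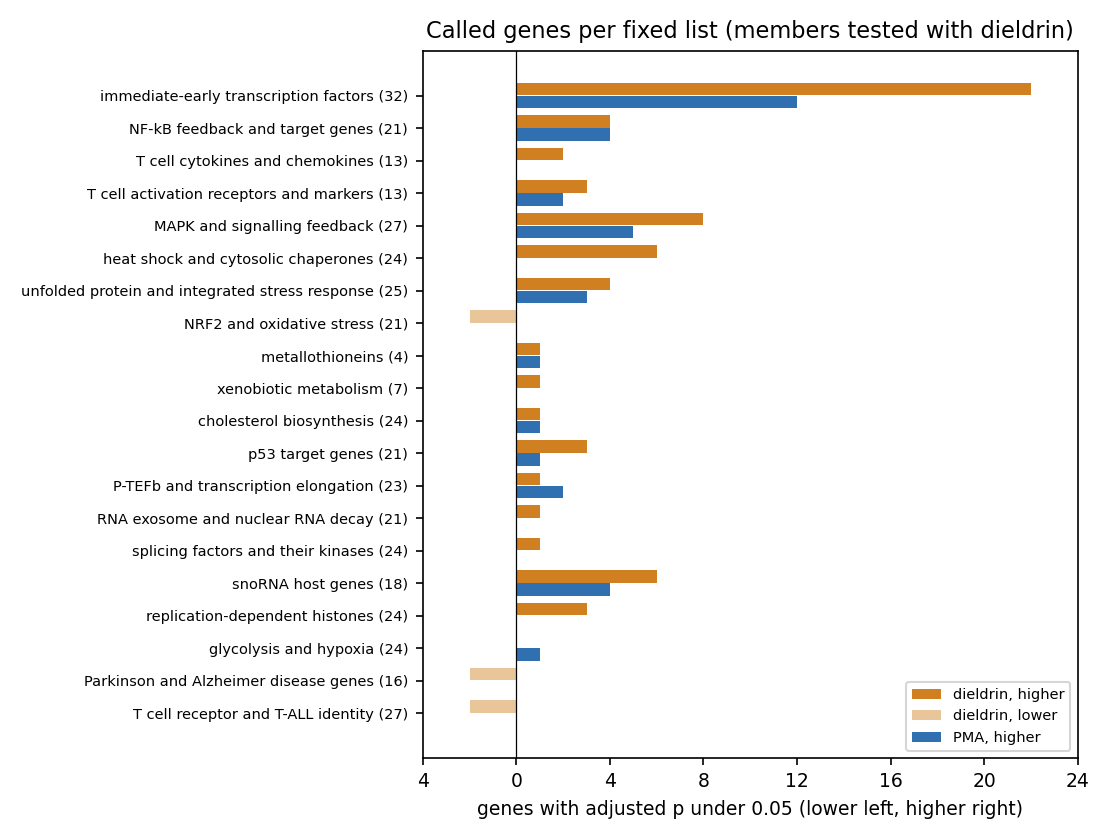
Bars count the genes of each fixed list (lists with at least 1 such gene) with an adjusted p under 0.05 in the authors' comparisons, higher to the right and lower to the left, for dieldrin (orange) and PMA (blue); the number in brackets is the members tested with dieldrin. The immediate-early list leads with 22 for dieldrin and 12 for PMA. The heat shock list has 6 and 0, the latter with the authors' statistic as it stands.

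The third comparison sets dieldrin against PMA, to tell which parts of the early response are common. Both treatments raised EGR1, NFKBIA, IER2 and MCL1, with no difference past the test. Dieldrin raised JUN and EGR2 further, and it raised NR4A3, which was not called with PMA. PMA raised CD83 and SGK1 further. PNPLA6, CBX6 and ATP13A2 were lower with dieldrin than with PMA.

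In all, 56 genes were called higher and 10 lower in both comparisons, where independent lists would share 1.28 and 0.179. The 10 lower genes were all long noncoding RNAs. A single gene, SLA, was called in opposite directions, lower with PMA and higher with dieldrin. Across the 17587 genes used for the simulation the unshrunken log2 changes of the 2 treatments correlated with a Pearson r of 0.554 and a Spearman rho of 0.411; genes are not independent replicates. Both comparisons use the same 3 DMSO libraries, and simulated unchanged groups against shared controls gave a mean r of 0.503 and at most 0 shared calls in 20 simulations. Over all these genes the covariance of the changes did not exceed the simulated one (0.0594 against 0.0658). Among genes with at least 1 CPM it did (0.0290 against 0.0114), but without the called genes it was 0.00769. The PMA statistic had a robust spread of 0.615 at means of 1000 to 10000, where a null statistic has 1. The simulated covariance, drawn from the same implied dispersion, may thus be too large, so it cannot settle how much is shared response. Part of the overlap may come from the shared DMSO libraries, which at 3 cannot be split.

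A direct test of the difference between the shrunken changes, which leaves out the covariance from the shared control, found 87 of 17612 genes different, 46 with dieldrin above PMA and 41 below. A setting chosen after the data were seen used unshrunken changes and the dispersion implied by the authors' values. With it 101 genes were above and 143 below. On simulated data without shrinkage and with the true dispersion supplied, 8.16% of the calls of this setting were false. With unshrunken changes and no covariance, also chosen after, 32 were above and 40 below, and 71 of these 72 were among the 87. Both settings take the error from the unshrunken change over the authors' statistic, which belongs to the shrunken change. Their values are therefore uncertain for genes with strong shrinkage, such as FOS and NR4A3. JUN differed by 2.06 in shrunken log2 units (SE 0.154, adjusted p 3.11e-37), EGR2 by 1.46 (6.26e-17), CD69 by 1.32 (4.81e-14) and FOS by 1.22 (1.80e-15), all higher with dieldrin. For FOS the unshrunken difference was 3.08, with an adjusted p of 0.0237 with the implied dispersion. With unshrunken changes and no covariance the adjusted p of FOS was 0.947. The call of FOS thus depends on how the error is worked out. NR4A3, outside the naming rule, differed by 1.52 (1.15e-20). CD83 was lower with dieldrin than with PMA by a difference of -0.76 (2.57e-07), and SGK1 by -0.76 (1.55e-05). PNPLA6, CBX6 and ATP13A2 differed by -0.92, -0.73 and -0.85, with adjusted p-values of 4.19e-07, 2.56e-06 and 8.12e-06. EGR1, NFKBIA, IER2 and MCL1 did not pass this test, with differences of -0.22, -0.16, 0.11 and 0.01 and standard errors of 0.164, 0.133, 0.144 and 0.0889. Of the heat shock genes, HSPA1B (0.53, adjusted p 0.00947) and HSPA1A (0.46, adjusted p 0.0425) passed and DNAJB1 (0.50, adjusted p 0.273) did not. With the implied dispersion HSPA1A missed the threshold (0.0699) while HSPA1B (0.00957) and DNAJB1 (0.00901) passed, and unshrunken without covariance none of the 3 did (1.00, 0.610 and 0.597). The unshrunken differences of these heat shock genes were larger than the shrunken ones. Of the 376 genes called with dieldrin and not with PMA, 65 passed the test of the difference, so most of them are not shown to respond to dieldrin alone.

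**Figure D2:**
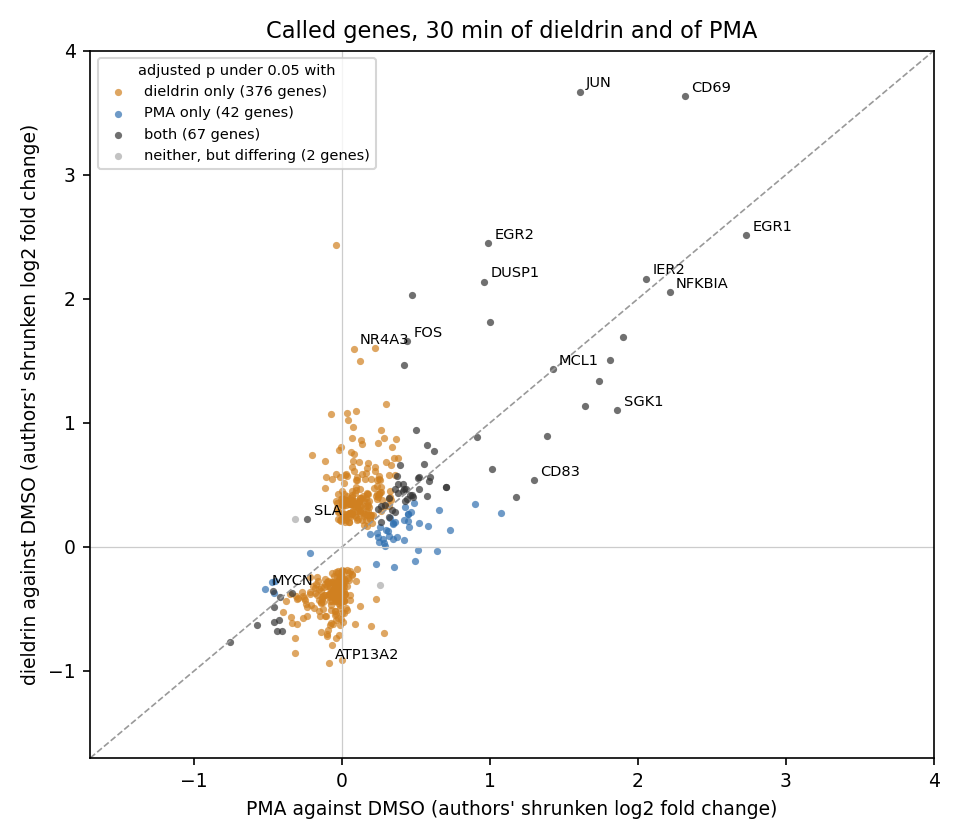
Each point is a gene called in either comparison or in the test of their difference, with the authors' shrunken log2 fold change of PMA against DMSO on the horizontal axis and of dieldrin against DMSO on the vertical axis; the dashed line marks equal change. EGR1, NFKBIA and MCL1 lie near the line, and JUN and EGR2 lie far above it.

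Markers of other cell types were checked as a sign of RNA from other cells. None of 6 B cell, 7 myeloid, 1 erythroid and platelet, and 4 fibroblast and epithelial markers tested passed the authors' test with dieldrin, and the counts at an unadjusted p under 0.05 and adjusted over the list alone were also 0. That test sets dieldrin against DMSO, so it would miss RNA of other cells present alike in both groups. The highest level within these lists was 34.6 CPM among B cell, 23.6 among myeloid, 0.0946 among erythroid and platelet and 2.0 among fibroblast and epithelial markers, against 834 in the T cell receptor and T-ALL list. The B cell and myeloid levels lie well above 1 CPM, and their source was not tested.

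The fourth comparison concerns sites of divergent transcription, where RNA is made in both directions, as at promoters and enhancers. The DMSO list holds 113689 sites covering 38.5 Mb and the dieldrin list 118474 sites covering 40.7 Mb, with median lengths of 254 and 255 bp. With 1 library per list there is no replicate error, and the intervals below are exact binomial (Clopper-Pearson) and cover counting error only. Of the DMSO sites 43.7% (95% interval 43.4 to 44.0) overlapped a dieldrin site by at least 1 bp, and 41.8% (41.5 to 42.1) of the dieldrin sites overlapped a DMSO site. After a shift by 100 kb, 6.51% of DMSO sites still overlapped. Shared sites lay near gene starts more often than unshared ones: 25.8% (25.4 to 26.2) of the shared dieldrin sites lay within 1 kb of an annotated start, against 9.73% (9.51 to 9.95) of those in the dieldrin list only and 10.2% (10.0 to 10.5) of those in the DMSO list only. Most sites lay elsewhere inside genes, 72.5% in either list.

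The 5 named sites of each list were picked as the nearest to a gene start, and all of them overlapped one. In the DMSO list, sites overlapping the annotated start of CD69 (chromosome 12, 9913489 to 9914061), DUSP1 (chromosome 5, 172197990 to 172198212), NFKBIA (chromosome 14, 35873219 to 35874181), IER2 (chromosome 19, 13261176 to 13261229) and PPP1R15A (chromosome 19, 49375459 to 49375666) all overlapped a dieldrin site. In the dieldrin list the start of JUN held a site (chromosome 1, 59249769 to 59249900) that overlapped no DMSO site. The dieldrin sites at the starts of MCL1 (chromosome 1, 150551140 to 150552251), IER2 (chromosome 19, 13261185 to 13261594), PPP1R15A (chromosome 19, 49375459 to 49375687) and DUSP2 (chromosome 2, 96810089 to 96811944) overlapped DMSO sites. By the order of the rule, no dieldrin site overlapped the annotated starts of CD69, DUSP1 and NFKBIA, and no DMSO site those of JUN and MCL1. Sites of the 2 lists could thus overlap each other without both reaching the start. Within 10 kb of the start or in the body, 19 of 41 named genes raised by dieldrin had more dieldrin than DMSO sites, 12 had fewer and 10 as many; of 11 named genes that it lowered, 2 had more, 7 fewer and 2 as many. EGR1 had 4 DMSO and 8 dieldrin sites, CD69 10 and 14, NFKBID 7 and 14, and ICOS 0 and 5, while JUN had 6 and 4, TNFAIP3 8 and 4, DNAJB1 11 and 8 and BRD2 5 and 2. Among control genes that were not called, GAPDH had 8 and 7, CD3E 3 and 4, and ACTB 12 and 7. Other uncalled genes shifted as well, such as IRF9 with 3 and 10 and POR with 15 and 9. The counts at single genes thus do not by themselves mark a response to dieldrin.

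Of the 246 genes higher with dieldrin, 89.4% had a site of the dieldrin list only within 10 kb, against a mean of 84.8% in 10000 random gene sets matched on mean expression (percentile 98.2). The number of such sites per gene went the other way, 4.496 against 4.676 (percentile 32.4; 99.5 when matched also on gene length), and that of the DMSO list only was 3.46 against 4.43 (0.04, or 16.9). For sites of the DMSO list only the share was 84.6% (percentile 22.1), and for shared sites 86.2% (percentile 99.1). Of the 197 lower genes, 88.3% had a site of the dieldrin list only (percentile 61.2), 86.3% one of the DMSO list only (percentile 13.4) and 90.9% a shared site (percentile 99.2). With a window of 1 kb the first percentile was 18.1 and the last 30.0, and several others moved as well. Matched also on gene length, the percentile for the dieldrin list only was 99.9 at the higher and 97.0 at the lower genes, and for the DMSO list only 54.2 and 66.2. Counted by part, the higher genes held 1221 DMSO and 1393 dieldrin sites inside their bodies, a gain of 0.699 ± 0.196 sites per gene (SE over genes), above the central 95% of random sets matched on expression and gene length (a matching chosen after the data were seen) from -0.224 to 0.455. The gain in the 10 kb upstream was 0.122 and in the 10 kb downstream 0.171, both inside the range of random sets. At the 197 lower genes the number inside the bodies went from 1302 to 1258, and at the 37 genes raised by PMA and not called with dieldrin it was 128 in both lists.

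**Figure D3:**
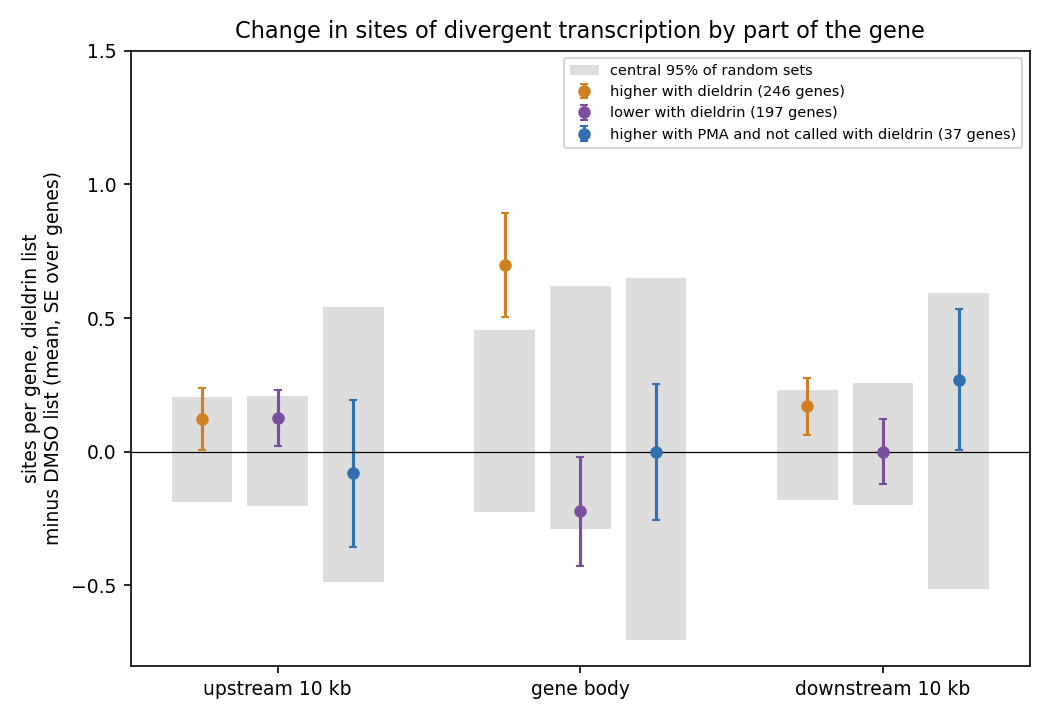
Points give the mean change in the number of sites per gene, dieldrin list minus DMSO list, with SE over genes, for 246 higher, 197 lower and 37 PMA-raised genes in 3 parts of the gene; grey bars span the central 95% of 10000 matched random sets. The higher genes' bodies, at 0.699, lie above their bar.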

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

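The rescaled statistic, the unshrunken 2-fold limit, the implied dispersion, the unshrunken difference, the other set-test settings and the matching on gene length were chosen after seeing the data; the other settings were planned before the data were examined. No paired analysis was possible because no values per library were used. For the same reason the other normalizations, other tools, a replicate block, leaving out replicates, splits of the samples, and an estimated correlation or fry for the lists were not run.

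The dieldrin count of 443 genes became 286 at an adjusted p under 0.01, 26 with a shrunken log2 fold change of 1 or more and 125 with an unshrunken one. The PMA count of 109 became 16 and 44 under the last 2 limits, and 383 (288 higher, 95 lower) when the statistic was rescaled to its own spread, among which all 109 were found. That rise has a visible reason: the statistic's robust spread with PMA was 0.615 for genes with means of 1000 to 10000 and 0.418 above 10000, where a null statistic has 1, so rescaling enlarges the statistic there. With dieldrin the rescaled count was 560 and held 421 of the 443. The dieldrin and PMA difference count of 87 became 14 for differences of 1 or more and 244 with the implied dispersion and covariance, which held 82 of the 87. With unshrunken changes and no covariance it was 72, holding 71 of them, and FOS, HSPA1A and HSPA1B lost their calls. For these genes the unshrunken differences were larger than the shrunken ones, so the calls were lost to a larger error. Fewer calls under stricter limits follow from their construction. The filter at 1 CPM and the adjustment over all listed genes left each of the 3 counts within 1.5 times, as did an adjusted p under 0.01 for the last 2 (73 and 66 genes).

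The correlation of 0.554 was 0.644 at 1 CPM or more and 0.777 at 10 or more. The covariance beyond the simulated one went from -0.00648 to 0.0176 and 0.0209. Without the called genes the covariance was 0.00769 and 0.00310 at these levels, below the simulated 0.0114 and 0.00582. Leaving out called genes takes out the largest changes by construction. The simulated values cover the called genes as well and may be too large. The comparison thus cannot show whether the uncalled genes share a response. Why the values moved with the level was not tested. Of 12 lists past the set test with dieldrin, 9, 8, 8 and 9 passed under a preset correlation of 0.05, of 0.1, ranks, and a filter at 1 CPM. For PMA the 10 lists became 10, 8, 9 (7 of the 10 among them) and 10. No list past the test reversed.

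The share of DMSO sites found in the dieldrin list was 17.9% with reciprocal overlap of 50%, 62.3% after extension by 500 bp and 41.0% among sites of at least the median length; the reverse share was 17.2%, 60.2% and 39.1%. The first follows from the stricter and the second from the looser rule; for the third the cause was not tested. Percentiles near genes depended on the window. For the higher genes and the dieldrin list only, 98.2 became 18.1 at 1 kb, 97.5 at 50 kb and 10.5 for the 26 genes with a shrunken change of 1 or more. For the DMSO list only, 22.1 became 0.01 at 1 kb, and for shared sites 99.1 became 67.6 at 1 kb and 25.8 for the 26 genes. For the lower genes and the dieldrin list only, 61.2 became 0.385 at 1 kb, for the DMSO list only 13.4 became 1.52 at 50 kb, and for shared sites 99.2 became 30.0 at 1 kb. Matched also on gene length, the 61.2 became 97.0 and the 13.4 became 66.2. The cause was not tested. No lower gene reached a shrunken change of 1, so that setting gave no value for them.

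Of the named genes with an adjusted p, 2 with dieldrin (NOTCH1 and RAG1) and 2 with PMA (PMAIP1 and HEXIM1) lost their call when the adjustment covered all listed genes, and 8 and 16 gained one with the rescaled statistic. The depth of single libraries, unknown here, limits what can be said of genes of low mean.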

Other observations

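The tests below on coding length, GC content, coding for membrane or secreted proteins and the amount of RNA were set before their results were seen, and the others were chosen after. The patterns were noticed in these data, so what is said of them is hypothesis. No split of the samples was possible without values per library.

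Some small RNA and histone genes, grouped after their values were seen, were called as well. The groups were not tested as sets. The libraries were poly(A)-enriched, so which forms of small RNA or histone RNA gave these reads is unknown. All 7 RNU1 and RNVU1 genes tested, named for U1 small nuclear RNA, had a positive change with dieldrin. Their median log2 change was 1.34, and 3 passed the authors' test. With PMA 0 of 7 passed, also at an unadjusted p under 0.05, and the median was -0.30; these genes are near-identical copies, so their single values are uncertain. Of the snoRNA and scaRNA genes, 7 of 108 rose with dieldrin and 7 of 83 with PMA. Among all histone genes listed by symbol, 8 of 61 rose with dieldrin and 0 of 58 with PMA, where 3 had an unadjusted p under 0.05. The difference between the treatments was not tested for these groups.

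Genes lower with dieldrin often encoded proteins with hydrophobic segments, as membrane and secreted proteins do: 85 of the 135 protein-coding ones (63.0%) had at least 1 segment, against a mean of 29.9% in random sets matched on mean expression, while among 180 higher ones the share was 23.3% against 33.6%. Matching also on coding length (random mean 33.4%) or on GC content (31.0%), or on both (35.4%), left the share of random sets reaching 63.0% at 0.0001, the smallest that 10000 draws can give, which argues against either trend as the whole source. The shared DMSO libraries would have lowered the same genes with PMA, but their median PMA change was -0.0314 log2 units (95% bootstrap interval -0.0551 to -0.0174), against an upper quartile of -0.33 with dieldrin. Expressed genes as a class moved a little the same way: the median was 0.00205 without a segment, -0.0246 with 1 or more and -0.0391 with 2 or more. With the median of its class taken off each gene, as for an even loss of membrane-bound RNA from the dieldrin samples, 115 lower protein-coding genes were left and 65 of them (56.5%) had a segment, against a random mean of 30.0%. The share of random sets reaching this was 0.0001. The class medians taken off were small beside the median of -0.447 in the 85 lower genes with a segment, so this share adds little to the sizes themselves. These sizes argue against an even loss as the whole source, while it stays open for the shift of the class and for part of the calls. Dieldrin may lower within 30 min a subset of RNAs that code for membrane or secreted proteins; an uneven loss of such RNAs during extraction stays open, as untested.

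Mitochondrial tRNA genes had a median log2 change of -1.02 with dieldrin over 20 genes, with an upper quartile of -0.73. Because the group was noticed first, it was set against all 975 groups of at least 10 tested genes whose symbols begin alike. Its score was -10.8, and 1 group stood off further. Groups whose symbols begin alike can contain smaller ones, and the group further off was not identified. A wider group that holds the tRNA genes is therefore not excluded. With changes permuted among genes of like expression, the most extreme score of any group had a 95th percentile of 4.003 in size. The share of permutations reaching the tRNA score was 0.0001, the smallest that 10000 can give. This argues against noise at low counts that is independent between genes. Permuting single genes breaks joint variation, so noise that the tRNA genes share within libraries stays open. The median of the mitochondrial tRNA genes with PMA was 0.0108 (95% bootstrap interval -0.12 to 0.16), which argues against the shared DMSO libraries. The median of 108 snoRNA and scaRNA genes was 0.36 with dieldrin (0.26 to 0.52), so these short RNAs showed no net loss. With PMA their median was 0.42 over 83 genes. A rise of these RNAs may have hidden a loss, so a loss of short RNAs from the dieldrin libraries is not decided. Mitochondrial mRNAs and rRNAs had a median of -0.18 (-0.32 to -0.09), which argues against an equal fall of all mitochondrial transcripts. A candidate explanation is a fall of newly made or unprocessed mitochondrial RNA, which reads at tRNA genes would show before long-lived mRNAs do; RNA turnover was not measured and this stays untested.

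The gain of dieldrin sites inside the genes that dieldrin raised lay at percentile 99.9 of random sets matched on expression and gene length, which argues against the longer dieldrin list as its source. Whether sites follow the amount of RNA from a gene cannot be told apart from other explanations: across 12444 uncalled genes, which are not independent replicates, the change in sites had a Spearman rho of 0.00260 with the log2 change (permutation p 0.773). The bound set beforehand read such a rho as evidence against that explanation, but it was wrong, because these genes hardly changed, with a robust spread of 0.0992 log2 units against a median of 0.78 in the raised genes; this was seen only after the result. The upstream gain lay at percentile 87.3, inside the range of random sets, which goes against a gain of regulatory sites around the genes by the bound set for it; that bound was wrong, because the gain of 0.122 has an SE of 0.115 over genes, too wide to exclude a value above the upper end of the range, 0.203, so this stays open as well. The raised genes may hold more sites because more RNA came from them, which 1 library per condition leaves undecided.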
